A study of Sus scrofa with 11 samples.

How the data were processed

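Total RNA had been isolated with Trizol from pig heart slices and made into TruSeq RNA libraries, per the labels. The deposited table gives one FPKM value per gene and library, that is fragments scaled to gene length and library size, as computed by the authors. The submitters' processing notes name Bowtie 0.12.2 and the build name mm8, a mouse build, with no role, while the gene identifiers are those of pig Ensembl genes. The counting tool, the annotation release, any filter on genes and the treatment of reads that fit more than 1 gene are not given in the sources used here. Close relatives such as MYH6 and MYH7, ACTC1, ACTA1 and ACTA2, heat shock gene HSPA1L, MT1X and ribosomal protein genes may share reads. Levels are thus uncertain to that extent. All 11 columns were matched to their samples by name.

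The table held 16319 genes, of which 9686 had a symbol, 6633 had none and 246 were at 0 in every library. FPKM values of a gene are whole multiples of a step, which allowed the reads behind them to be recovered. Every value above 0 came out as a whole number of reads within a tolerance of 0.01, for 16073 genes. On simulated data, the same steps returned every read number for 99.88% of 16028 genes, and for 99.98% of those with 30 reads or more, with a largest relative error of a library total of 2.04e-12. A floor of 3 reads over a group was used as the upper limit for a gene with 0 reads. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. FPKM values summed to 682020.0 to 1112101.5 per library.

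Genes with a mean FPKM of at least 1 over all libraries were tested, 12625 in all and 8157 with a symbol. Values were taken as log2(FPKM + 1), so log2 fold changes of genes with low FPKM understate their ratios. One linear model with the 4 groups as terms was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend, 7 residual and 5.89 prior degrees of freedom) in R 4.3.3, and 5 comparisons were read from it. Day 2, day 6 and day 10 were each compared with day 0, day 6 with day 2, and day 10 with day 6. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within a comparison with a threshold of 0.05. Adjusted p-values of genes are named limma adjusted p. No replicate block was used, since the labels do not say that a replicate number marks an animal. Of 15 pairs of libraries with the same number, 9 had a correlation of residuals above 0.1, with a range of -0.552 to 0.469, and 5 of 11 libraries correlated best with a library of their own number. For day 6 and day 10 alone, the 3 pairs with the same number were at 0.275, 0.250 and 0.180, so a shared source of these libraries stays open.

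37 lists of genes for heart muscle functions, metabolism, matrix, stress responses and markers of other cell types were fixed before the data were examined, together with the tests, the filters and the choice of genes to name. The 33 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, which compares a list with the remaining genes, and beside it with a correlation estimated from the data and with fry. With an estimated correlation, 0 lists passed in each comparison, with a smallest adjusted p of 0.0672. For each list, the number of members past the threshold is also given adjusted over the list alone. Genes were named by a rule with 3 parts. A panel of 16 genes was named for the comparisons with day 0 whatever its values, of which 11 were tested. MYH7, ATP2A2, PLN, NPPA and COL1A1 had no symbol match in the tested table and were not analysed here. Up to 6 higher and 6 lower genes with the largest log2 fold change were named, with 3 and 3 for the comparisons between cultured days, given a mean FPKM of at least 5 in the higher group and no overlap between libraries. Up to 3 members with the smallest p were named from each list that passed or had at least 3 changed members. Where the text cites a library's own value or a group's reads, it was chosen after the values were seen. Some genes picked by this rule are not reported here.

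On simulated groups with known changes, limma found 31.8% of 8-fold changes for day 2 against day 0, 47.6% for day 6, 47.8% for day 10, 40.4% for day 6 against day 2 and 62.2% for day 10 against day 6, and 4.94% to 7.43% of its calls were false. Fitted log2 fold changes had a median of 0.783 to 0.840 of the true ones. For 4-fold changes it found 4.8% to 19.5%. Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter or a mean FPKM of at least 5, 3 other scalings of the libraries (an equal total, median ratio and quantile), only the compared groups in the fit, eBayes without trend or robust, array weights, a replicate block, and leaving out each library in turn. Where a library is left out of day 2, the remaining library is assumed to vary like those of the other groups. Leaving out the 2 libraries with the fewest genes, alone or with median ratio scaling, and limma voom on the recovered reads were added after the data had been seen. Recovery of reads, tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions and raw reads were not used here.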

Results

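RNA was sequenced from 11 libraries of heart slices from Yorkshire pigs aged 3 months. 3 libraries came from slices at day 0, and the rest came from slices kept in stimulated culture, with 2 libraries at day 2, 3 at day 6 and 3 at day 10. The labels do not say what the stimulation was or whether replicates came from separate animals. Limma p-values thus measure only spread between these samples. Preset camera and permutation p-values compare genes. The reads behind the table numbered 13909343, 12624627 and 16404585 at day 0 and 16253357 and 12872835 at day 2. They numbered 16775191, 12470365 and 16164182 at day 6 and 14598192, 11701413 and 16262521 at day 10.

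Day 0 replicate 2 and day 2 replicate 1 stood apart from the remaining libraries. They had 4536 and 4017 genes at 0, against 1310 to 2331 in the 9 others. The median FPKM over all genes was 0.60 in day 0 replicate 2 and 2.42 in day 2 replicate 1, and it lay between 2.90 and 6.70 in the 9 others. Genes of the mitochondrial genome took 16.55%, 4.53% and 22.1% of reads at day 0, 19.44% and 21.68% at day 2, 15.05%, 19.7% and 14.51% at day 6, and 9.85%, 4.04% and 3.53% at day 10. The 10 genes with most reads took from 11.61% of reads in day 10 replicate 3 to 30.93% in day 0 replicate 2.

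**Figure D1:**
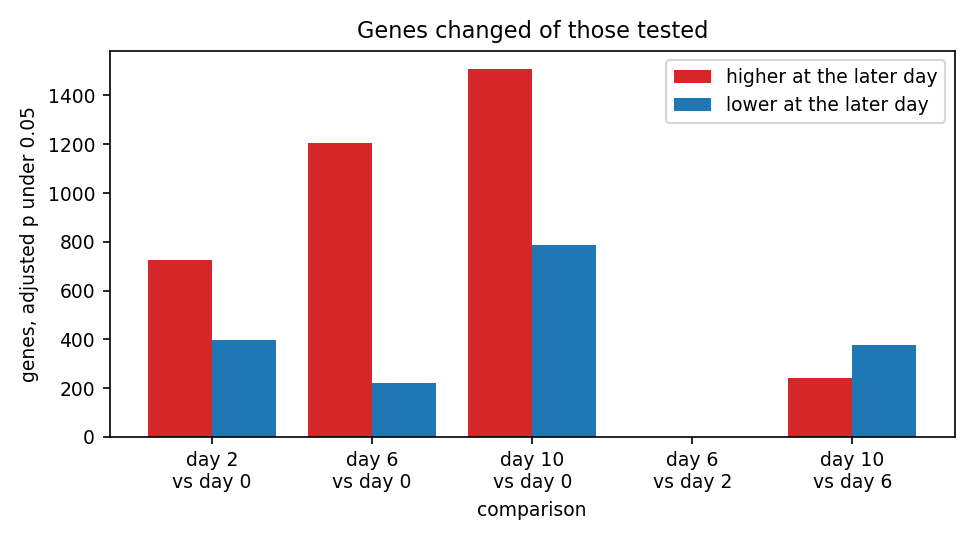
Bars give the number of genes (y axis, of 12625 tested) whose limma adjusted p was under 0.05 in each of the 5 comparisons (x axis), higher at the later day in red and lower at the later day in blue. Day 10 against day 0 had the tallest bars with 1508 higher and 787 lower genes, and day 6 against day 2 had 0 of each. The balance between red and blue bars moved with the scaling of the libraries, which put 596 of 866 genes lower at day 6 with median ratio scaling.

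The day 2 comparison asked how slices after 2 days in stimulated culture differed from day 0 slices. Lower genes included 10 of 13 measured sarcomere genes and 8 of 21 oxidative phosphorylation genes. Higher genes included 7 of 13 matrix protease genes and 7 of 10 oxidant response genes. None of the list calls held with an estimated correlation, with adjusted p = 0.124, 0.124, 0.198 and 0.198 for these 4. MYH6 (ENSSSCG00000002029), which encodes alpha myosin heavy chain, averaged 17069 ± 9197 FPKM at day 0 (SD, n = 3) and 733 ± 528 FPKM at day 2 (SD, n = 2), a log2 fold change of -4.56 ± 0.68 (SE, limma adjusted p = 0.00258). MMP9 (ENSSSCG00000007436), a gelatinase that degrades extracellular matrix, averaged 0.474 ± 0.655 FPKM at day 0 and 326 ± 114 FPKM at day 2, a log2 fold change of 7.84 ± 0.86 (limma adjusted p = 5.87e-04). For both genes the day 0 and day 2 libraries did not overlap.

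Of 13 measured sarcomere genes, 10 fell at day 2 and 3 did not pass the test, with 13 lower when adjusted over the list alone. The median log2 fold change of the list was -3.84 (camera adjusted p = 2.92e-17, adjusted p = 0.124 with an estimated correlation). Cardiac alpha-actin ACTC1 (ENSSSCG00000004803) went from 5446 ± 2446 to 263 ± 137 FPKM (log2 fold change -4.34 ± 0.63, limma adjusted p = 0.00228). Myosin-binding protein C MYBPC3 went from 1158 ± 638 to 45.0 ± 40.7 FPKM (log2 fold change -4.80 ± 0.70, limma adjusted p = 0.00238), and the Z-disc protein gene ACTN2 had a log2 fold change of -3.88 ± 0.51. Skeletal alpha-actin ACTA1 fell by a log2 fold change of -3.92 ± 0.67 (limma adjusted p = 0.00442). Cardiac troponin T TNNT2 fell from 12134 ± 654 to 1876 ± 2190.4 FPKM (limma adjusted p = 0.0179), and NPPB, the precursor of B-type natriuretic peptide, fell from 185 ± 83.3 to 24.6 ± 28.2 FPKM (limma adjusted p = 0.0142). Without day 2 replicate 2, the log2 fold change was -1.82 for TNNT2 (limma adjusted p = 0.168) and -1.94 for NPPB (limma adjusted p = 0.145).

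Of 21 oxidative phosphorylation genes, 8 fell at day 2 and 13 did not pass, with 17 lower when adjusted over the list alone (median -1.53, camera adjusted p = 3.15e-15, adjusted p = 0.124 with an estimated correlation). SLC25A4, the ADP/ATP carrier, went from 3523 ± 1081 to 249 ± 173 FPKM (limma adjusted p = 0.00370). Of 18 fatty acid oxidation genes, 4 fell, and 7 when adjusted over the list alone (camera adjusted p = 1.73e-09, adjusted p = 0.188 with an estimated correlation), among them the muscle carnitine palmitoyltransferase CPT1B with a log2 fold change of -4.24 ± 0.60. The tricarboxylic acid cycle list had 2 lower genes of 16, and 4 when adjusted over the list alone (camera adjusted p = 1.77e-08, adjusted p = 0.188 with an estimated correlation). Mitochondrially encoded transcripts were not lower, with 0 of 12 past the test, also when adjusted over the list alone, and a median of 0.64 (camera adjusted p = 0.898). The calcium handling and ion channel list had 2 lower genes of 9, and 5 when adjusted over the list alone (camera adjusted p = 9.77e-06, adjusted p = 0.226 with an estimated correlation). These 2 were the hERG channel gene KCNH2, with a log2 fold change of -3.28 ± 0.55, and the potassium channel subunit gene KCNIP2, with -3.99 ± 0.73. The KCNIP2 call ended without day 2 replicate 2 (log2 fold change -3.33, limma adjusted p = 0.0667). Among 14 cardiac transcription factor genes, 4 fell, and 5 when adjusted over the list alone (camera adjusted p = 2.65e-06, adjusted p = 0.261 with an estimated correlation). The ventricular factor IRX4 was one of these, with a log2 fold change of -2.94 ± 0.53 that became -2.39 without day 2 replicate 1 (limma adjusted p = 0.0623).

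The matrix protease list had 7 higher genes of 13 at day 2, and 8 when adjusted over the list alone (median 2.59, camera adjusted p = 2.79e-05, adjusted p = 0.198 with an estimated correlation). Next to MMP9, these included the aggrecanase ADAMTS4, from 0.813 ± 0.932 to 247 ± 276 FPKM, and urokinase PLAU, from 5.09 ± 3.36 to 136 ± 73.1 FPKM. The oxidant response list had 7 higher genes of 10, and 9 when adjusted over the list alone (camera adjusted p = 6.81e-06, adjusted p = 0.198 with an estimated correlation). Sulfiredoxin SRXN1 rose by a log2 fold change of 6.21 ± 0.65 and the quinone reductase NQO1 by 4.12 ± 0.59. The list for the unfolded protein and integrated stress response had 7 higher genes of 12, and 11 when adjusted over the list alone (camera adjusted p = 1.86e-05, adjusted p = 0.249 with an estimated correlation). Asparagine synthetase ASNS went from 4.83 ± 0.852 to 56.9 ± 5.34 FPKM (limma adjusted p = 0.00258). The inflammatory list had 5 higher genes of 11, and 6 when adjusted over the list alone (camera adjusted p = 4.13e-04, adjusted p = 0.261 with an estimated correlation). The monocyte-attracting chemokine CCL2 went from 23.7 ± 6.30 to 1569 ± 302 FPKM and the inducible cyclooxygenase PTGS2 from 0.211 ± 0.228 to 16.2 ± 6.01 FPKM. The glycolysis list moved both ways with 4 higher and 4 lower genes of 18, and 6 and 4 when adjusted over the list alone (camera adjusted p = 0.813). ENO1, the enolase of non-muscle tissue, rose from 97.0 ± 23.5 to 1483 ± 108 FPKM.

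The largest day 2 changes outside the lists were CYP1A1, a target of the aryl hydrocarbon receptor, from 0.179 ± 0.227 to 142 ± 99.9 FPKM, and, among lower genes, the inward rectifier channel gene KCNJ4 from 293 ± 83.3 to 6.38 ± 2.24 FPKM. Log2 fold changes were -5.11 ± 0.63 for ASB2, -5.03 ± 0.62 for DAPL1, -4.94 ± 0.62 for the glycogen phosphorylase gene PYGB, -4.91 ± 0.56 for the melusin gene ITGB1BP2 and -4.81 ± 0.74 for cholecystokinin CCK. Panel genes that did not pass at day 2 had log2 fold changes of 1.01 ± 0.98 for POSTN, 0.46 ± 1.23 for FN1, 0.11 ± 0.98 for GJA1, -1.74 ± 0.98 for COL3A1 and -2.95 ± 1.31 for RYR2 (limma adjusted p between 0.172 and 0.961). The signs for POSTN, FN1 and GJA1 were negative without day 0 replicate 2, at -0.22, -0.76 and -1.05, and those of FN1 and GJA1 also without day 2 replicate 2 and under median ratio or quantile scaling.

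At day 2 camera also set further lists apart from the remaining genes. Endothelial markers ranked above the rest (2 of 13 genes past the test, 4 adjusted over the list alone, median 1.87, camera adjusted p = 0.0161, adjusted p = 0.634 with an estimated correlation). Heat shock genes ranked above the rest (3 of 12 genes and 1 lower past the test, 6 and 1 lower adjusted over the list alone, median 1.68, camera adjusted p = 0.0201, adjusted p = 0.534 with an estimated correlation). Immediate early genes ranked above the rest (4 of 12 genes past the test, 4 adjusted over the list alone, median 1.02, camera adjusted p = 0.0214, adjusted p = 0.634 with an estimated correlation). Cholesterol synthesis genes ranked above the rest (0 of 15 genes past the test, 0 adjusted over the list alone, median 1.53, camera adjusted p = 0.0161, adjusted p = 0.634 with an estimated correlation). Intercalated disc genes ranked below the rest (0 of 12 genes past the test, 0 adjusted over the list alone, median -0.77, camera adjusted p = 0.0215, adjusted p = 0.634 with an estimated correlation). Load and fetal programme genes ranked below the rest (3 of 12 genes past the test, 3 adjusted over the list alone, median -0.59, camera adjusted p = 0.00127, adjusted p = 0.249 with an estimated correlation). Fibroblast markers ranked below the rest (2 of 11 genes past the test, 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.0317, adjusted p = 0.370 with an estimated correlation). Lymphocyte markers ranked below the rest (1 of 8 genes past the test, 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.0114, adjusted p = 0.370 with an estimated correlation). Interferon response genes ranked below the rest (0 of 14 genes past the test, 0 adjusted over the list alone, median -0.45, camera adjusted p = 0.0192, adjusted p = 0.634 with an estimated correlation). Complement and antigen presentation genes ranked below the rest (0 of 7 genes past the test, 0 adjusted over the list alone, median -0.97, camera adjusted p = 0.0167, adjusted p = 0.188 with an estimated correlation).

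In the limma fit, 1124 of 12625 genes passed at day 2, 727 higher and 397 lower, and all of them changed at least 2-fold. The median log2 fold change over all genes was 0.51, and it was 0.00 with median ratio scaling and 0.11 with quantile normalization, which gave 337 higher and 816 lower genes and 707 higher and 1018 lower genes. That median was 0.10 without day 0 replicate 2, 0.04 without day 2 replicate 2 and 0.96 without day 2 replicate 1. The count was 1763 without day 0 replicate 2 (842 higher and 921 lower), 719 without day 0 replicate 3, 360 without day 2 replicate 1, 399 without day 2 replicate 2 and 1375 without both libraries with few genes. With only the day 0 and day 2 libraries in the fit it was 17, which kept 7 of the 63 called genes among those selected for naming, with MMP9, CYP1A1, CCL2, ITGB1BP2, ASB2 and KCNJ4 among them. 20 of 33 lists passed camera, and 10 of them lost the call when a library was left out. Without day 2 replicate 1 these were the intercalated disc (camera adjusted p = 0.107), interferon (0.107), heat shock (0.448) and immediate early (0.296) lists. Without day 2 replicate 2 these were the load and fetal programme (0.207), fibroblast (0.144), endothelial (0.0975), lymphocyte (0.321), complement (0.303) and cholesterol synthesis (0.13) lists. Leaving out day 0 replicate 1 or 3 ended the intercalated disc call (0.101 and 0.0825), day 0 replicate 3 the interferon call (0.228), and day 0 replicate 2 the fibroblast (0.0655), lymphocyte (0.148), complement (0.0572) and immediate early (0.087) calls. The fibroblast list also missed with median ratio scaling (0.0589) and quantile normalization (0.0841), and the lymphocyte list with quantile normalization (0.0502). With a mean FPKM of at least 5 the intercalated disc, heat shock and cholesterol synthesis lists missed (0.0703, 0.0703 and 0.0629). With array weights the endothelial, lymphocyte, complement and immediate early lists did (0.0966, 0.228, 0.0512 and 0.0823), and with no filter the complement (0.0639) and fibroblast (0.05) lists.

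**Figure D2:**
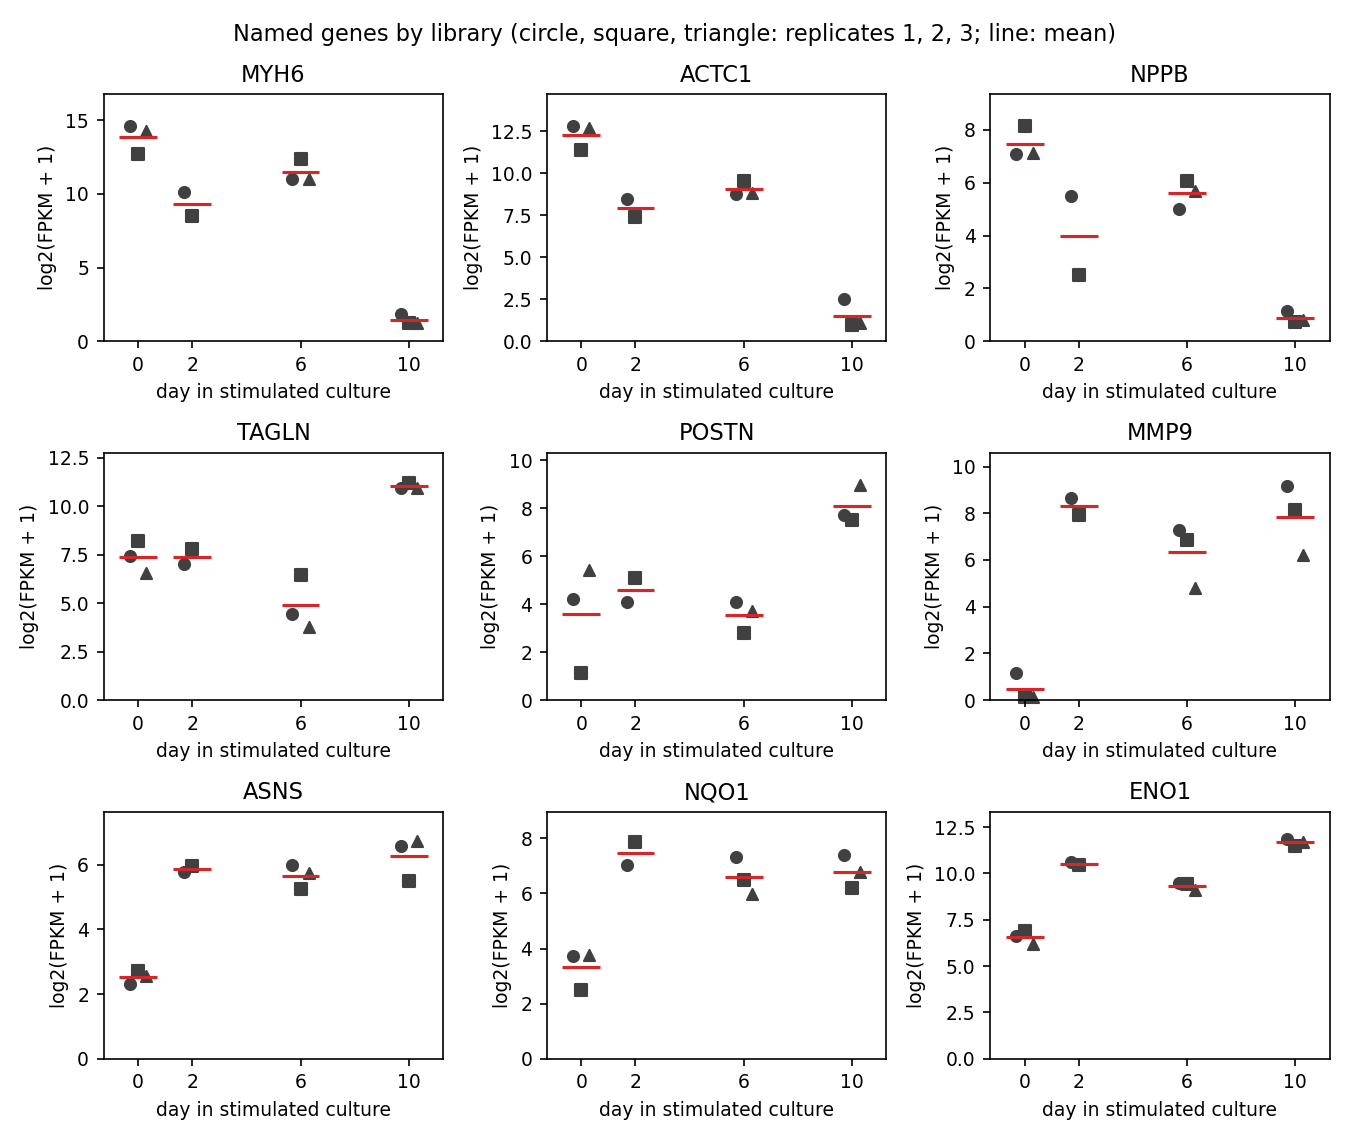
Points give log2(FPKM + 1) of 9 genes (y axis) in each of the 11 libraries, placed by day in culture (x axis), with marks for replicates and lines for the mean of each day. MYH6 and ACTC1 averaged 17069 ± 9197 and 5446 ± 2446 FPKM at day 0 and 1.74 ± 0.686 and 2.22 ± 2.10 FPKM at day 10 (SD, n = 3), and TAGLN averaged 40.4 ± 41.0 FPKM at day 6 and 2104 ± 253 FPKM at day 10.

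At day 6 against day 0, the question was whether the slices still differed after 6 days of stimulated culture. Higher genes included 11 of 12 genes of the unfolded protein and integrated stress response and 8 of 10 oxidant response genes, and lower genes included 4 of 13 sarcomere genes. These list calls did not hold with an estimated correlation (adjusted p = 0.253, 0.253 and 0.119). ADAMTS4 averaged 194 ± 66.9 FPKM at day 6 against 0.813 ± 0.932 FPKM at day 0 (SD, n = 3 each), a log2 fold change of 6.82 ± 0.74 (limma adjusted p = 7.43e-04). ACTC1 averaged 548 ± 184 FPKM against 5446 ± 2446 FPKM, a log2 fold change of -3.23 ± 0.56 (limma adjusted p = 0.00743), which became -3.08 without day 6 replicate 1 (limma adjusted p = 0.0525).

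The list for the unfolded protein and integrated stress response had 11 higher genes of 12 at day 6, the same number when adjusted over the list alone (median 3.03, camera adjusted p = 3.32e-06, adjusted p = 0.253 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 83.2 ± 62.5 to 1865 ± 1476 FPKM (limma adjusted p = 0.00865), a call that ended without day 6 replicate 1 (log2 fold change 4.13, limma adjusted p = 0.0623). ASNS went from 4.83 ± 0.852 to 50.6 ± 13.2 FPKM (limma adjusted p = 0.00281). The heat shock list had 7 higher genes of 12, and 9 when adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.437 with an estimated correlation). The chaperone gene HSPH1 was among them with a log2 fold change of 3.24 ± 0.61, and 3.11 without day 6 replicate 1 (limma adjusted p = 0.0707). The oxidant response list had 8 higher genes of 10, also 8 when adjusted over the list alone (camera adjusted p = 2.49e-04, adjusted p = 0.253 with an estimated correlation). SRXN1 rose by 5.96 ± 0.58 and GCLC, an enzyme of glutathione synthesis, by 3.50 ± 0.57 on the log2 scale.

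In the matrix protease list, 8 of 13 genes rose at day 6, and 10 when adjusted over the list alone (camera adjusted p = 2.89e-04, adjusted p = 0.253 with an estimated correlation). MMP9 averaged 99.3 ± 65.2 FPKM at day 6, and PLAU rose by a log2 fold change of 4.09 ± 0.55. The inflammatory list had 5 higher genes of 11, and 7 when adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.307 with an estimated correlation), with CCL2 at 1069 ± 555 FPKM. Among immediate early genes, 5 of 12 rose, and 8 when adjusted over the list alone (camera adjusted p = 0.00289, adjusted p = 0.437 with an estimated correlation). The AP-1 subunit gene FOSL1 rose by 4.21 ± 0.49, MYC by 3.78 ± 0.58 and JUNB by 3.36 ± 0.49 on the log2 scale. Of 15 cholesterol synthesis genes, 7 rose, and 13 when adjusted over the list alone (camera adjusted p = 0.00135, adjusted p = 0.437 with an estimated correlation). Squalene epoxidase SQLE had a log2 fold change of 2.79 ± 0.67, and it did not pass without day 6 replicate 1 or 3 (limma adjusted p = 0.115 and 0.0923). The metallothionein gene MT1X and the zinc finger gene ZFAND2A were among the highest changes, with log2 fold changes of 7.01 ± 0.92 and 5.57 ± 0.81. MT1X stood at 7804 FPKM in day 6 replicate 2 and at 538 and 578 FPKM in the other day 6 libraries.

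Of 13 sarcomere genes, 4 fell at day 6 and 9 did not pass, with 11 lower when adjusted over the list alone (median -2.17, camera adjusted p = 3.74e-15, adjusted p = 0.119 with an estimated correlation). Of 21 oxidative phosphorylation genes, 5 fell, and 11 when adjusted over the list alone (median -1.20, camera adjusted p = 3.69e-18, adjusted p = 0.105 with an estimated correlation). The log2 fold changes of SLC25A4, CPT1B and KCNIP2 were -2.70 ± 0.57, -2.63 ± 0.54 and -3.16 ± 0.65. Each passed in the full fit and missed without day 6 replicate 1 (limma adjusted p = 0.0999, 0.0926 and 0.0889) and without day 6 replicate 3 (0.0682, 0.0612 and 0.0668). MYH6 averaged 3151 ± 1857 FPKM at day 6 with a log2 fold change of -2.39 ± 0.61 (limma adjusted p = 0.0299), and ACTA1 averaged 4023 ± 1204 FPKM with -2.04 ± 0.60 (limma adjusted p = 0.0459). The MYH6 call ended without day 0 replicate 1 or 3, day 6 replicate 1 or 3, or day 10 replicate 2 (limma adjusted p = 0.0634, 0.0637, 0.141, 0.111 and 0.0525), and with quantile normalization (0.11). The ACTA1 call ended without any 1 of the 9 libraries of day 0, 6 and 10, with limma adjusted p up to 0.182 without day 6 replicate 1. It also ended with median ratio scaling (-3.19, limma adjusted p = 0.0546), quantile normalization (-1.08, 0.152), a pseudocount of 0.1 (0.0602), no filter (0.0601) and only the compared groups (0.0548). TNNT2 and NPPB did not pass, with log2 fold changes of -2.02 ± 0.71 and -1.86 ± 0.67 (limma adjusted p = 0.0773 and 0.0825). Nor did RYR2 (-0.42 ± 1.17), GJA1 (0.49 ± 0.88), FN1 (0.86), POSTN (-0.04 ± 0.88) or COL3A1 (-1.33 ± 0.88), with limma adjusted p between 0.275 and 0.980. Without day 0 replicate 2, the values of GJA1 and FN1 were -0.67 and -0.35, and RYR2 passed at -2.30. RYR2 was positive without day 0 replicate 1 or 3, at 0.54 and 0.52, and POSTN without day 0 replicate 1 or 3 or day 6 replicate 2, at 0.28, 0.88 and 0.33.

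Other lower genes at day 6 included the cell surface and matrix gene CLEC3B, with a log2 fold change of -3.34 ± 0.56, the lipid droplet gene PLIN5, from 15.6 ± 2.82 to 0.382 ± 0.336 FPKM, and RXRG, a retinoid receptor gene, from 86.3 ± 34.2 to 4.79 ± 5.73 FPKM. KCNJ4, ASB2 and DAPL1 had log2 fold changes of -3.66 ± 0.50, -3.78 ± 0.56 and -3.79 ± 0.55. The cardiac transcription factor and tricarboxylic acid cycle lists passed camera as lower than the remaining genes with 0 and 0 genes past the test, also when adjusted over the list alone (camera adjusted p = 2.89e-04 and 4.72e-07, adjusted p = 0.391 and 0.210 with an estimated correlation). Their median log2 fold changes were -0.52 and -0.54, while the median over all genes was 0.88 (0.46 without day 0 replicate 2 and 0.51 with array weights). Mitochondrially encoded transcripts had 0 of 12 genes past the test, also when adjusted over the list alone, and a median of 0.56 (camera adjusted p = 0.547).

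At day 6 camera also set further lists apart from the remaining genes. Calcium handling and ion channel genes ranked below the rest (1 of 9 genes past the test, 1 adjusted over the list alone, median -0.83, camera adjusted p = 2.84e-04, adjusted p = 0.278 with an estimated correlation). Load and fetal programme genes ranked below the rest (1 of 12 genes and 1 higher past the test, 5 and 2 higher adjusted over the list alone, median -0.05, camera adjusted p = 0.00452, adjusted p = 0.278 with an estimated correlation). Fatty acid oxidation genes ranked below the rest (2 of 18 genes and 1 higher past the test, 6 and 1 higher adjusted over the list alone, median -0.67, camera adjusted p = 2.29e-08, adjusted p = 0.210 with an estimated correlation). Fibroblast markers ranked below the rest (2 of 11 genes past the test, 2 adjusted over the list alone, median -0.58, camera adjusted p = 3.11e-04, adjusted p = 0.210 with an estimated correlation). Smooth muscle and pericyte markers ranked below the rest (1 of 12 genes past the test, 1 adjusted over the list alone, median -0.67, camera adjusted p = 2.89e-04, adjusted p = 0.307 with an estimated correlation). Lymphocyte markers ranked below the rest (1 of 8 genes past the test, 1 adjusted over the list alone, median -0.40, camera adjusted p = 8.96e-04, adjusted p = 0.278 with an estimated correlation). Interferon response genes ranked below the rest (0 of 14 genes past the test, 0 adjusted over the list alone, median -0.18, camera adjusted p = 0.0123, adjusted p = 0.574 with an estimated correlation). Complement and antigen presentation genes ranked below the rest (1 of 7 genes past the test, 1 adjusted over the list alone, median -0.55, camera adjusted p = 7.53e-04, adjusted p = 0.119 with an estimated correlation). Endothelial markers did not pass camera, with 3 of 13 genes higher, 3 adjusted over the list alone (median 1.66, camera adjusted p = 0.0592, adjusted p = 0.656 with an estimated correlation). Nor did macrophage and monocyte markers (camera adjusted p = 0.0636).

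In the limma fit, 1428 genes passed at day 6, 1206 higher and 222 lower. With median ratio scaling the median over all genes was 0.12 and the split 270 higher and 596 lower, and with quantile normalization 0.07 and 676 higher and 934 lower. The count was 119 without day 6 replicate 1, 578 without day 6 replicate 2, 352 without day 6 replicate 3, 830 without day 0 replicate 3 and 804 without day 10 replicate 2, and 1980 (1352 higher) without both libraries with few genes. With only the day 0 and day 6 libraries in the fit it was 536. 19 of 33 lists passed camera, and the interferon list lost its call without day 0 replicate 3 (camera adjusted p = 0.326). The interferon list had a mean log2 fold change of -0.00887 (limma fry adjusted p = 0.909), so camera set it below the remaining genes and not below day 0. The heat shock list missed with median ratio scaling (camera adjusted p = 0.0665), the load and fetal programme list with quantile normalization (0.213), the immediate early list with array weights (0.0565), and the lymphocyte list without both libraries with few genes under median ratio scaling (0.12).

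By day 10, all 13 measured sarcomere genes had fallen below day 0, and 17 of 25 extracellular matrix genes were higher. Neither list call held with an estimated correlation (adjusted p = 0.0672 and 0.415). MYH6 averaged 1.74 ± 0.686 FPKM at day 10 against 17069 ± 9197 FPKM at day 0 (SD, n = 3 each), a log2 fold change of -12.44 ± 0.61 (SE, limma adjusted p = 2.21e-07). The matrix gene POSTN (periostin) averaged 298 ± 178 FPKM against 20.1 ± 20.4 FPKM, a log2 fold change of 4.49 ± 0.88 (limma adjusted p = 0.00383). For both genes the 3 day 10 libraries did not overlap with the 3 day 0 libraries. This comparison asked how slices at the last cultured time point differed from day 0.

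The sarcomere list had 13 lower genes of 13 at day 10, the same number when adjusted over the list alone, and a median log2 fold change of -9.02 (camera adjusted p = 2.31e-28, adjusted p = 0.0672 with an estimated correlation). ACTC1 averaged 2.22 ± 2.10 FPKM (log2 fold change -10.78 ± 0.56, limma adjusted p = 2.42e-07) and TNNT2 7.54 ± 2.53 FPKM (log2 fold change -10.51 ± 0.71, limma adjusted p = 2.46e-06). Log2 fold changes were -10.36 ± 0.80 for the ventricular light chain gene MYL3, -9.71 ± 0.63 for MYBPC3 and -8.79 ± 0.46 for ACTN2. The load and fetal programme list had 7 lower genes of 12, also when adjusted over the list alone (camera adjusted p = 2.90e-07, adjusted p = 0.110 with an estimated correlation). NPPB fell from 185 ± 83.3 to 0.866 ± 0.316 FPKM and ACTA1 from 16242 ± 3194 to 15.2 ± 7.41 FPKM. Of 9 calcium handling and ion channel genes, 6 fell (camera adjusted p = 1.58e-05, adjusted p = 0.220 with an estimated correlation). Adjusted over the list alone, 6 were lower and 1 was higher. KCNH2, KCNIP2 and the triadin gene TRDN had log2 fold changes of -4.44 ± 0.49, -5.85 ± 0.65 and -5.54 ± 0.69. The calcium release channel gene RYR2 fell from 67.8 ± 57.8 to 0.241 ± 0.265 FPKM (limma adjusted p = 0.0185). This call ended without day 0 replicate 1 or 3 or any of the 3 day 10 libraries (limma adjusted p between 0.0538 and 0.0664). The cardiac transcription factor list had 6 lower genes of 14, and 8 when adjusted over the list alone (camera adjusted p = 2.33e-07, adjusted p = 0.266 with an estimated correlation), with TBX5 from 21.1 ± 5.14 to 0.999 ± 0.425 FPKM.

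Of 21 oxidative phosphorylation genes, 12 fell at day 10, and 14 when adjusted over the list alone (median -1.75, camera adjusted p = 3.01e-15, adjusted p = 0.0875 with an estimated correlation). SLC25A4 fell from 3523 ± 1081 to 42.0 ± 19.6 FPKM. The tricarboxylic acid cycle list had 7 lower genes of 16, and 12 when adjusted over the list alone (camera adjusted p = 6.75e-10, adjusted p = 0.110 with an estimated correlation). The fatty acid oxidation list had 8 lower genes of 18, and 9 when adjusted over the list alone (camera adjusted p = 1.64e-08, adjusted p = 0.171 with an estimated correlation), such as CPT1B with a log2 fold change of -6.47 ± 0.54. Mitochondrially encoded transcripts passed camera as lower with 0 of 12 genes past the test, also when adjusted over the list alone (camera adjusted p = 8.65e-05, adjusted p = 0.410 with an estimated correlation). These transcripts took 3.53% to 9.85% of reads at day 10 and 4.53% in day 0 replicate 2. In the glycolysis list, 6 genes rose and 4 fell of 18, and 8 and 5 when adjusted over the list alone (camera adjusted p = 0.722). The non-muscle enolase ENO1 rose from 97.0 ± 23.5 to 3305 ± 392 FPKM, and the muscle forms ENO3 and PGAM2 fell from 4674 ± 3389 to 12.9 ± 10.1 and from 1459 ± 1366 to 2.64 ± 0.571 FPKM.

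Among extracellular matrix genes, 17 of 25 were higher and 1 lower at day 10, and 22 and 1 when adjusted over the list alone (median 2.96, camera adjusted p = 1.15e-06, adjusted p = 0.415 with an estimated correlation). The list's median log2(FPKM + 1) was 1.81 in day 0 replicate 2, the library with the most genes at 0, and 5.50 and 4.86 in the other day 0 libraries. Biglycan BGN rose from 77.9 ± 40.5 to 2464 ± 1938 FPKM and fibromodulin FMOD by a log2 fold change of 4.08 ± 0.56. Fibronectin FN1 passed with a log2 fold change of 3.99 (limma adjusted p = 0.0253), and missed without day 0 replicate 2, day 10 replicate 2 or day 10 replicate 3 (limma adjusted p = 0.053, 0.085 and 0.115). COL3A1 and the connexin 43 gene GJA1 did not pass, with log2 fold changes of 2.39 ± 0.88 and 1.83 ± 0.88 (limma adjusted p = 0.0781 and 0.168). Matrix proteases rose in 9 of 13 genes, also when adjusted over the list alone (camera adjusted p = 3.60e-05, adjusted p = 0.208 with an estimated correlation), with MMP9 at 311 ± 253 FPKM. The oxidant response list rose in 8 of 10 genes, also when adjusted over the list alone (camera adjusted p = 3.60e-05, adjusted p = 0.220 with an estimated correlation), with the peroxiredoxin gene PRDX1 from 38.1 ± 8.08 to 1023 ± 606 FPKM. In the stress response list, 8 of 12 genes rose (camera adjusted p = 1.76e-04, adjusted p = 0.333 with an estimated correlation), and 10 were higher and 1 lower when adjusted over the list alone. The serine synthesis genes PSAT1 and PHGDH rose by 5.59 ± 0.61 and 4.94 ± 0.50 on the log2 scale. Cytosolic ribosomal protein genes rose in 7 of 13 cases, and 9 when adjusted over the list alone (camera adjusted p = 0.00101, adjusted p = 0.383 with an estimated correlation). With median ratio scaling the list missed (camera adjusted p = 0.0984). RPS18 and RPL5, with log2 fold changes of 2.60 ± 0.57 and 2.11 ± 0.46, did not pass under that scaling (limma adjusted p = 0.214 for each).

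At day 10 the Wnt-binding protein gene SFRP2 rose from 0.214 ± 0.0474 to 283 ± 227 FPKM and the EGF receptor ligand gene AREG from 0.0700 ± 0.0759 to 409 ± 568 FPKM. The neurotensin gene NTS had 0 reads over the day 0 libraries and 3231 over the day 10 libraries, with 220, 76.7 and 39.2 FPKM in these 3. By a floor of 3 reads over the day 0 group, for counting error only, it was at least 382-fold higher in the lowest of them, and at least 1091-fold at their mean, which rests on day 10 replicate 1. CCL2 reached 2286 ± 1001 FPKM. Markers of other cell types had means on both sides of 0 at day 10. The mean log2 fold change was 0.74 over endothelial, 0.44 over smooth muscle and pericyte, 0.37 over fibroblast, -0.31 over macrophage and monocyte, and -0.54 over lymphocyte markers. The fibroblast list had 2 higher and 2 lower genes of 11, also when adjusted over the list alone, and did not pass camera (adjusted p = 0.795). Vimentin VIM rose to 3341 ± 1036 FPKM, which did not pass under median ratio scaling (limma adjusted p = 0.0517), and PI16 and CLEC3B fell with log2 fold changes of -4.65 ± 0.71 and -5.22 ± 0.56.

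At day 10 camera also set further lists apart from the remaining genes. Hypoxia response genes ranked above the rest (6 of 14 genes past the test, 6 adjusted over the list alone, median 1.84, camera adjusted p = 0.0341, adjusted p = 0.578 with an estimated correlation). Inflammatory cytokine and adhesion genes ranked above the rest (6 of 11 genes past the test, 6 adjusted over the list alone, median 2.22, camera adjusted p = 0.00978, adjusted p = 0.415 with an estimated correlation). Cell cycle genes ranked above the rest (2 of 12 genes past the test, 7 adjusted over the list alone, median 1.77, camera adjusted p = 0.01002, adjusted p = 0.565 with an estimated correlation). Cholesterol synthesis genes ranked above the rest (3 of 15 genes past the test, 7 and 1 lower adjusted over the list alone, median 1.67, camera adjusted p = 0.0341, adjusted p = 0.578 with an estimated correlation). Intercalated disc genes ranked below the rest (4 of 12 genes past the test, 4 adjusted over the list alone, median -0.78, camera adjusted p = 0.00796, adjusted p = 0.558 with an estimated correlation). Macrophage and monocyte markers ranked below the rest (2 of 14 genes and 1 higher past the test, 2 and 1 higher adjusted over the list alone, median -0.44, camera adjusted p = 0.0468, adjusted p = 0.558 with an estimated correlation). Lymphocyte markers ranked below the rest (3 of 8 genes and 1 higher past the test, 4 and 1 higher adjusted over the list alone, median -1.07, camera adjusted p = 0.00897, adjusted p = 0.383 with an estimated correlation). Interferon response genes ranked below the rest (0 of 14 genes past the test, 0 adjusted over the list alone, median -0.60, camera adjusted p = 0.00796, adjusted p = 0.565 with an estimated correlation).

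In the limma fit, 2295 genes passed at day 10, 1508 higher and 787 lower, or 912 and 1245 with median ratio scaling and 1356 and 1427 with quantile normalization. The median over all genes was 0.51, and 0.10 without day 0 replicate 2. The count was 1460 without day 10 replicate 2, 1310 with only the day 0 and day 10 libraries in the fit, and 3413 (1838 higher) without both libraries with few genes. Of 23 lists past camera, 7 lost the call when a library was left out. The interferon list did so without day 0 replicate 3 (camera adjusted p = 0.103) and the cell cycle list without day 10 replicate 1 (0.113). Without day 10 replicate 3 the cholesterol synthesis (0.103), growth factor (0.0554), hypoxia (0.0745), macrophage (0.567) and lymphocyte (0.0568) lists did, the last 3 also without day 0 replicate 2 (0.134, 0.151 and 0.139). The growth factor and macrophage lists also missed with median ratio scaling (0.0739 and 0.0874). With quantile normalization the growth factor, macrophage, hypoxia and lymphocyte lists missed (0.0572 for each), and with a mean FPKM of at least 5 the inflammatory list (0.0821) and the hypoxia, macrophage, cell cycle and cholesterol synthesis lists (0.106 for each) did. With array weights the cell cycle (0.0999), cholesterol synthesis (0.0742), hypoxia (0.118), macrophage (0.225) and lymphocyte (0.274) lists missed, and with voom the cholesterol synthesis and hypoxia lists (0.0504 and 0.0528). The macrophage list also missed with a pseudocount of 5, no filter or only the compared groups (0.0602, 0.0579 and 0.0532).

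**Figure D3:**
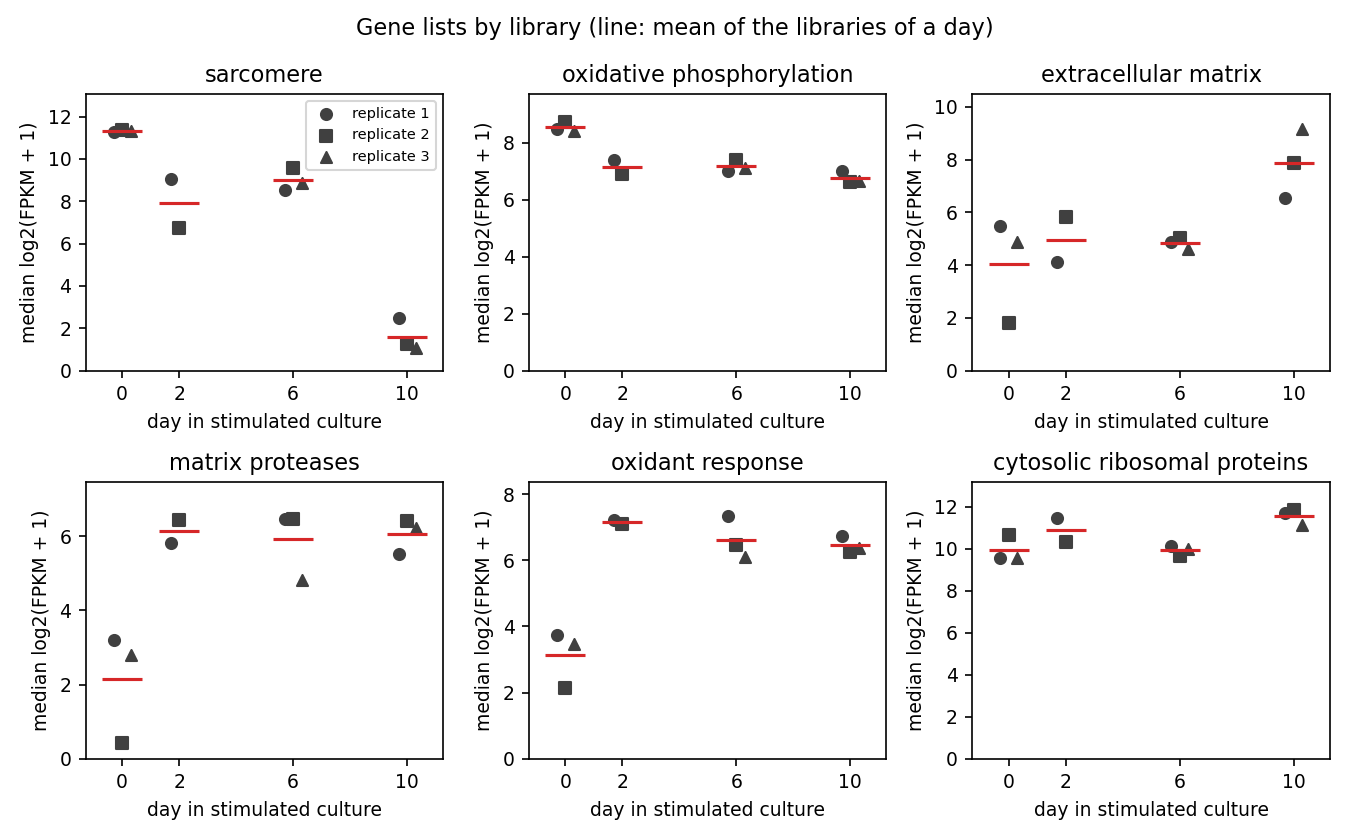
Points give the median log2(FPKM + 1) of 6 gene lists (y axis) in each of the 11 libraries, placed by day in culture (x axis), with marks for replicates and red lines for the mean of each day. The sarcomere list lay between 11.29 and 11.37 at day 0, at 9.07 and 6.73 at day 2, between 8.55 and 9.57 at day 6 and between 1.07 and 2.49 at day 10.

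Between day 2 and day 6, no gene passed the limma test, and 511 genes had an unadjusted p under 0.05. limma voom on recovered reads also called 0 genes. ACTN2 averaged 236 ± 77.1 FPKM at day 6 (SD, n = 3) and 45.0 ± 18.9 FPKM at day 2 (SD, n = 2), a log2 fold change of 2.37 ± 0.51 (limma adjusted p = 0.584). IRX4 averaged 7.29 ± 1.71 and 0.577 ± 0.816 FPKM, with 2.48 ± 0.53 on the log2 scale (limma adjusted p = 0.584), and SLC16A3, a lactate transporter gene, had -2.36 ± 0.56 (limma adjusted p = 0.748). This step compared the earliest with the middle cultured time point.

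Camera placed 14 lists apart from the remaining genes between day 2 and day 6, with 0 members past the test over all genes. The sarcomere list was higher (median 1.49, camera adjusted p = 2.29e-07, adjusted p = 0.658 with an estimated correlation), with 3 of 13 genes higher when adjusted over the list alone. The cytosolic ribosomal protein list was lower (median -0.94, camera adjusted p = 5.15e-10, adjusted p = 0.640 with an estimated correlation), with 0 of 13 genes lower when adjusted over the list alone. The extracellular matrix and matrix protease lists were called lower although their medians were 0.05 and 0.15, since all genes had a median of 0.36 (camera adjusted p = 0.0320 and 0.0448, adjusted p = 0.849 and 0.658 with an estimated correlation). The mean of the matrix protease list was -0.12. The median over all genes was -0.04 without day 2 replicate 1 and 0.77 without day 2 replicate 2. Each of the 14 calls ended without at least 1 library. Without day 2 replicate 2, 3 lists passed, and the sarcomere list did not (camera adjusted p = 0.879). The ribosomal list missed without day 2 replicate 1 (camera adjusted p = 0.0995).

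Between day 2 and day 6 camera also set further lists apart from the remaining genes. Calcium handling and ion channel genes ranked above the rest (0 of 9 genes past the test, 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.0120, adjusted p = 0.658 with an estimated correlation). Intercalated disc genes ranked above the rest (0 of 12 genes past the test, 0 adjusted over the list alone, median 0.98, camera adjusted p = 0.0189, adjusted p = 0.708 with an estimated correlation). Cardiac transcription factor genes ranked above the rest (0 of 14 genes past the test, 1 adjusted over the list alone, median 0.87, camera adjusted p = 0.00416, adjusted p = 0.658 with an estimated correlation). Load and fetal programme genes ranked above the rest (0 of 12 genes past the test, 2 adjusted over the list alone, median 0.56, camera adjusted p = 0.0464, adjusted p = 0.658 with an estimated correlation). Tricarboxylic acid cycle genes ranked above the rest (0 of 16 genes past the test, 0 adjusted over the list alone, median 0.84, camera adjusted p = 0.0177, adjusted p = 0.658 with an estimated correlation). Fatty acid oxidation genes ranked above the rest (0 of 18 genes past the test, 0 adjusted over the list alone, median 0.92, camera adjusted p = 0.00666, adjusted p = 0.658 with an estimated correlation). Glycolysis genes ranked below the rest (0 of 18 genes past the test, 1 adjusted over the list alone, median -0.11, camera adjusted p = 0.00666, adjusted p = 0.658 with an estimated correlation). Smooth muscle and pericyte markers ranked below the rest (0 of 12 genes past the test, 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.0154, adjusted p = 0.660 with an estimated correlation). Cell cycle genes ranked below the rest (0 of 12 genes past the test, 0 adjusted over the list alone, median -0.49, camera adjusted p = 3.90e-04, adjusted p = 0.658 with an estimated correlation). Oxidant response genes ranked below the rest (0 of 10 genes past the test, 0 adjusted over the list alone, median -0.27, camera adjusted p = 0.00888, adjusted p = 0.658 with an estimated correlation).

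From day 6 to day 10, 12 of 13 sarcomere genes fell and 8 of 25 extracellular matrix genes rose. Neither list call held with an estimated correlation (adjusted p = 0.132 and 0.519). This step compared the middle with the last cultured time point. MYH6 fell from 3151 ± 1857 to 1.74 ± 0.686 FPKM (SD, n = 3 each), a log2 fold change of -10.05 ± 0.61 (SE, limma adjusted p = 3.16e-06). TAGLN, which encodes the smooth muscle protein transgelin, rose from 40.4 ± 41.0 to 2104 ± 253 FPKM, a log2 fold change of 6.13 ± 0.64 (limma adjusted p = 1.70e-04). For both genes the day 6 and day 10 libraries did not overlap.

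Of 13 sarcomere genes, 12 fell between day 6 and day 10, and 13 when adjusted over the list alone (median -7.16, camera adjusted p = 3.88e-22, adjusted p = 0.132 with an estimated correlation). Log2 fold changes were -8.49 ± 0.71 for TNNT2, -8.19 ± 0.80 for MYL3, -7.55 ± 0.56 for ACTC1 and -7.27 ± 0.46 for ACTN2. In the load and fetal programme list, 5 of 12 genes fell, and 6 when adjusted over the list alone (camera adjusted p = 1.03e-04, adjusted p = 0.372 with an estimated correlation). Filamin C FLNC fell from 938 ± 317 to 12.1 ± 9.98 FPKM and NPPB from 49.4 ± 17.2 to 0.866 ± 0.316 FPKM. The calcium handling and ion channel list had 3 lower genes of 9, and 5 when adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.627 with an estimated correlation), among them TRDN with -3.87 ± 0.69 and KCNH2 with -3.08 ± 0.49. The desmosome gene DSP fell from 39.5 ± 12.6 to 0.0591 ± 0.0764 FPKM. Mitochondrially encoded transcripts passed camera as lower with 0 genes past the test and 7 of 12 when adjusted over the list alone (camera adjusted p = 3.52e-04, adjusted p = 0.627 with an estimated correlation). Their share of reads was 14.51% to 19.7% at day 6 and 3.53% to 9.85% at day 10. ENO3, PGAM2 and CPT1B had log2 fold changes of -5.87 ± 0.74, -5.65 ± 0.74 and -3.84 ± 0.54.

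The extracellular matrix list had 8 higher genes of 25 from day 6 to day 10, and 14 when adjusted over the list alone (median 2.55, camera adjusted p = 1.11e-13, adjusted p = 0.519 with an estimated correlation). BGN rose from 176 ± 75.7 to 2464 ± 1938 FPKM and FMOD by a log2 fold change of 4.35 ± 0.56. POSTN rose by 4.52 ± 0.88, and by 4.16 without day 6 replicate 2, where the call ended (limma adjusted p = 0.054). The smooth muscle and pericyte list had 2 higher genes of 12, TAGLN and ACTA2, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.0108, adjusted p = 0.627 with an estimated correlation). Smooth muscle alpha-actin ACTA2 rose from 7.49 ± 8.75 to 484 ± 412 FPKM. TAGLN stood at 21.0, 87.5 and 12.8 FPKM in the day 6 libraries, below its 92.9 to 297 FPKM at day 0. The growth factor list had 3 higher genes of 13, and 5 when adjusted over the list alone (camera adjusted p = 8.34e-04, adjusted p = 0.587 with an estimated correlation), with the insulin-like growth factor binding protein genes IGFBP6 and IGFBP4 up by 5.44 ± 0.71 and 2.57 ± 0.43 on the log2 scale. Cytosolic ribosomal protein genes rose in 2 of 13 cases, and 9 when adjusted over the list alone (camera adjusted p = 1.49e-10, adjusted p = 0.316 with an estimated correlation). These were RPS18 and RPS23, with log2 fold changes of 2.17 ± 0.57 and 2.45 ± 0.64. Both calls ended without day 0 replicate 1 or 3, any 1 day 6 library, or day 10 replicate 1 or 2, with limma adjusted p from 0.0596 to 0.199 and from 0.0573 to 0.206. They also ended with median ratio scaling (0.165 for each), a pseudocount of 0.1 (0.0548 and 0.0579) and no filter (0.062 and 0.0637), and that of RPS18 with quantile normalization (0.0546). SFRP2, AREG and NTS had the largest increases at log2 fold changes of 6.54 ± 0.75, 7.11 ± 0.86 and 6.39 ± 0.59, where NTS had 2 reads over the day 6 libraries, so its value depends on the pseudocount.

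Between day 6 and day 10 camera also set further lists apart from the remaining genes. Fibroblast markers ranked above the rest (2 of 11 genes past the test, 3 and 1 lower adjusted over the list alone, median 1.62, camera adjusted p = 0.00566, adjusted p = 0.519 with an estimated correlation). Cell cycle genes ranked above the rest (1 of 12 genes past the test, 1 adjusted over the list alone, median 1.59, camera adjusted p = 0.00213, adjusted p = 0.627 with an estimated correlation). Intercalated disc genes ranked below the rest (2 of 12 genes past the test, 5 adjusted over the list alone, median -1.09, camera adjusted p = 0.0349, adjusted p = 0.670 with an estimated correlation). Cardiac transcription factor genes ranked below the rest (2 of 14 genes past the test, 2 adjusted over the list alone, median -1.49, camera adjusted p = 0.00298, adjusted p = 0.627 with an estimated correlation). Tricarboxylic acid cycle genes ranked below the rest (1 of 16 genes past the test, 6 adjusted over the list alone, median -1.05, camera adjusted p = 0.00298, adjusted p = 0.627 with an estimated correlation). Fatty acid oxidation genes ranked below the rest (2 of 18 genes past the test, 5 and 1 higher adjusted over the list alone, median -0.88, camera adjusted p = 0.0349, adjusted p = 0.627 with an estimated correlation). Immediate early genes ranked below the rest (1 of 12 genes past the test, 6 adjusted over the list alone, median -1.54, camera adjusted p = 0.00862, adjusted p = 0.627 with an estimated correlation).

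In the limma fit, 619 genes passed between day 6 and day 10, 241 higher and 378 lower, or 303 and 283 with median ratio scaling and 625 and 505 with quantile normalization. The count was 292, 309 and 281 without day 6 replicates 1, 2 and 3, 362 and 273 without day 10 replicates 1 and 2, 1544 without day 0 replicate 2, 1903 with only the day 6 and day 10 libraries in the fit, and 2524 (787 higher) without both libraries with few genes. Of 15 lists past camera, 5 lost the call when a library was left out: the fibroblast and smooth muscle lists without day 10 replicate 3 (camera adjusted p = 0.0569 and 0.0735), the immediate early list without day 6 replicate 2 (0.0883), the intercalated disc list without day 10 replicate 1 or 3 (0.0578 and 0.0569), and the fatty acid oxidation list without day 6 replicate 2 or day 10 replicate 2 or 3 (0.0841, 0.064 and 0.0796). With a mean FPKM of at least 5 the intercalated disc and cell cycle lists missed (0.0829 and 0.123). With a pseudocount of 5 the calcium handling, intercalated disc and fatty acid oxidation lists did (0.112, 0.0753 and 0.0677), and so they did with array weights (0.0907, 0.0527 and 0.0527), as did the cell cycle list (0.0652).

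Of the higher genes at day 6 and at day 10, 562 were shared where independent draws would share 144.1, and of the lower genes 201 were shared where 13.8 would be, while 4 genes went opposite ways. Independent draws leave out the shared day 0 libraries. Unchanged groups simulated against the same simulated day 0 libraries shared a mean of 0.01 calls for day 6 and day 10 and 0 for other pairs. These groups varied gene by gene, with no changed gene and no shift of a whole library. Few calls can arise there, so shared calls cannot show what the shared day 0 libraries add. Day 2 and day 6 shared 561 higher and 190 lower genes (69.4 and 7 if independent), and day 2 and day 10 shared 522 and 363 (86.8 and 24.7 if independent). Across the 12625 genes, which are not independent replicates, the fold changes of day 6 and day 10 had a Pearson r of 0.66 and a Spearman rho of 0.60. These comparisons used the same 3 day 0 libraries, and the simulated unchanged groups gave an r of 0.50. The covariance was 0.902 above that of 100 such simulations (0.202). 3 day 0 libraries could not be split with at least 2 in each comparison, so part of the excess of shared genes may come from the shared day 0 libraries. With 1 day 0 library in one comparison and the other 2 in the other, the 6 ways gave an r of 0.21 to 0.65 and a covariance of 0.555 to 1.05, the lowest with day 0 replicate 2 alone in the day 6 comparison. For day 2 and day 6 the r was 0.85, with 0.31 to 0.80 in such splits and 0.447 in simulated unchanged groups. For day 2 and day 10 it was 0.81, with 0.45 to 0.71 and 0.448.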

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

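The counts of other splits of the libraries and the test of reads taken by a few genes were planned before the results were seen, and the remaining tests of this part were chosen after. Among genes reported here and named for day 6 or day 10 against day 0, 53 differed between these days by limma's test of the difference. Of these, 12 had opposite signs against day 0, called or not. Their day 6 values ran from -3.26 for ACTA2 to 3.29 for FLNC, with some near 0 (POSTN -0.04, HSPB8 0.13). Genes named for other comparisons alone, such as RPS23, were not counted. Groups of 3 were too small for a test of single outlying samples. As log2 differences of day 10 from day 6, the lower values were -10.05 for MYH6, -8.49 for TNNT2, -8.19 for MYL3, -8.00 for ACTA1, -7.55 for ACTC1, -7.27 for ACTN2, -7.16 for MYBPC3, -6.42 for FLNC, -5.87 for ENO3, -5.65 for PGAM2, -5.51 for MT1X, -5.29 for MYOM2, -5.23 for HSPB8, -5.22 for DSP, -4.71 for NPPB, -4.61 for CXCL2 and -4.15 for KCNJ4. Further lower values were -3.93 for SYNPO2L, -3.87 for TRDN, -3.84 for CPT1B, -3.72 for SLC25A4, -3.08 for KCNH2, -2.99 for ASB2, -2.88 for IRX4, -2.69 for KCNIP2, -2.65 for CSF1R, -2.58 for ACAA2, -2.19 for DAPL1, -2.16 for IDH2, -2.11 for BAG3, -1.92 for CRY2 and -1.83 for ESRRA. The higher values were 2.04 for P4HA2, 2.17 for RPS18, 2.21 for IGFBP7, 2.33 for ENO1, 2.34 for PSAT1, 2.55 for VIM, 2.57 for IGFBP4, 2.89 for BHLHE41, 3.14 for PHGDH, 3.52 for BGN, 3.62 for CCNB1, 3.71 for COL3A1, 3.87 for GZMA, 4.35 for FMOD, 4.52 for POSTN, 5.44 for IGFBP6, 6.11 for ACTA2, 6.13 for TAGLN, 6.39 for NTS, 6.54 for SFRP2 and 7.11 for AREG. Of the 53 differences, 35 stayed past the threshold without any 1 library and none turned sign. The 18 that did not stay were those of CXCL2, KCNIP2, CSF1R, ACAA2, DAPL1, IDH2, BAG3, CRY2, ESRRA, P4HA2, RPS18, IGFBP7, PSAT1, VIM, BHLHE41, CCNB1, COL3A1 and POSTN, with a highest limma adjusted p from 0.0515 for CSF1R without day 6 replicate 2 to 0.199 for CCNB1 without day 10 replicate 1.

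Sarcomere transcripts were lower at day 10 than at day 0 with a median of -9.02 over the list. The scaling of the FPKM values is argued against as the cause, since the median was -9.71 with median ratio scaling, with an SD of 2.39 over the members and a range of -13.12 to -4.16. A lower share of cardiomyocytes with the remaining cell types unchanged may be a cause and cannot be told apart from lower transcription in the cells. It would raise the markers of other cell types alike, and at day 10 against day 0 the means of 5 such lists differed by 1.29, from -0.54 for lymphocytes to 0.74 for endothelium (permutation p = 0.51 over 10000 shuffles of the members), which decides nothing because members went both ways, with log2 fold changes of -5.22 for CLEC3B, -4.65 for PI16, -2.96 for CSF1R and -2.44 for CD2 against 3.13 for VIM and 3.52 for GZMA. From day 6 to day 10 the sarcomere median was -7.16. The means differed by 2.10, from -1.04 for endothelium to 1.07 for smooth muscle (permutation p = 0.01, or 0.0557 without day 10 replicate 3). Of 12 smooth muscle markers only TAGLN (6.13) and ACTA2 (6.11) passed. A lower share stays open beside an untested effect of time in culture.

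More genes were higher than lower at day 6 against day 0, at 84.5% of calls. Day 0 replicate 2, which had the most genes at 0, is argued against as the whole cause. Without it, 67.4% of calls were higher, while leaving out other libraries gave 77.2% to 89.7% with an SD of 3.59. The scaling of the values to the library total may be a cause and cannot be told apart from a general rise. With median ratio scaling 31.2% of calls were higher, but that scaling moves the median over all genes from 0.88 to 0.12 by its construction.

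Day 0 replicate 2 and day 2 replicate 1 had fewer genes above 0 than the 9 other libraries. At equal depth they had 11754 and 12281 genes against 13906 to 14869 in the others, which argues against sequencing depth. Without the 10 genes with most reads, again at equal depth, they had 11773 and 12267 against 13835 to 14801, which argues against these 10 genes as the cause. Reads held by a larger set of genes were not tested. The state of the RNA or the library preparation and a biological difference between slices were not tested.

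Other splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real split, so no share under 0.05 can be had. For genes, the real split gave 1428 at day 6 against day 0, 2295 at day 10 against day 0 and 619 at day 10 against day 6, and the highest other split gave 0 in each, so 1 of 10 splits gave as many. For lists, the real split gave 19, 23 and 15, the highest other split gave 19, 16 and 18, and 2, 1 and 3 of 10 splits gave as many.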

How the results depend on the processing

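Runs without the 2 libraries with the fewest genes and with voom were chosen after seeing the data. Of 9695 alternative values of named genes, 8535 kept their direction and their side of the threshold, 811 lost the call, 306 gained it and 43 turned sign. Of 2451 list values, 2213 kept both, 234 lost the call, 91 of them with an estimated correlation, and 4 turned. The correlation of day 6 and day 10 fold changes stayed between 0.600 and 0.698 in its 26 alternatives, within 1 SD (0.0866) between single libraries. Of 135 counts of genes, 100 stayed within 1.5 times. The cause of the shifts below was not tested. Runs without a library or with only the compared groups hold fewer samples, and median ratio and quantile scalings shift all genes of a library. Depth limits genes with few reads, such as NTS at day 6.

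At day 2, genes changed numbered 721 with an equal total, 1725 with quantile normalization, 17 with only the compared groups and 360 to 1763 without any 1 library. At day 6 they numbered 942 with a pseudocount of 0.1, 866 with median ratio scaling, 536 with only the compared groups, 6632 with array weights, 780 with voom and 119 to 1515 without any 1 library. At day 10 they numbered 1310 with only the compared groups, 5469 with array weights, 3633 without the 2 libraries with median ratio scaling and 1460 to 2700 without any 1 library. Between day 2 and day 6 they numbered 4 without the 2 libraries and 0 to 2 without any 1 library. Between day 6 and day 10 they numbered 1130 with quantile normalization, 1903 with only the compared groups, 5958 with array weights, 2524 without the 2 libraries, 2139 without them with median ratio scaling and 273 to 1544 without any 1 library. Lists changed numbered 16 to 21, 19 to 22, 18 to 23, 3 to 18 and 11 to 19 without any 1 library in these 5 comparisons, and 0 in each with an estimated correlation.

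No named gene called in the fit of all libraries turned sign. At day 2 (limma adjusted p 0.361 to 0.969 where the sign turned), POSTN (1.01) was -0.22 to 1.93 without any 1 library and -0.35 without the 2 libraries with median ratio scaling. FN1 (0.46) was -0.80 to 1.71 without any 1 library, -0.21, -0.16 and -0.77 with median ratio scaling, quantile normalization and array weights, and -0.13 without the 2 libraries with median ratio scaling. GJA1 (0.11) was -1.15 to 1.37, and -0.67, -0.23, -0.91 and -0.43 in the same order. At day 6 (limma adjusted p 0.0822 to 0.948 where the sign turned), FN1 (0.86) was -0.35 to 1.55 without any 1 library, -0.13, -0.17 and -0.39 with median ratio scaling, quantile normalization and array weights, -0.35 without the 2 libraries and -0.92 with median ratio scaling as well. GJA1 (0.49) was -0.67 to 1.14, -0.64 with median ratio scaling, -0.42 with array weights, -0.67 without the 2 libraries and -1.26 with median ratio scaling as well. IFIT5 (1.21) was -0.088 to 2.11, -0.088 without the 2 libraries and -0.65 with median ratio scaling as well. STAT2 (0.98) was 0.19 to 1.40, -0.079 with quantile normalization and -0.36 without the 2 libraries with median ratio scaling. POSTN (-0.04) was -1.27 to 0.88, 0.13 with a pseudocount of 0.1, 0.20 with an equal total and 0.11 with voom, and RYR2 (-0.42) was -2.30 to 0.54. Between day 2 and day 6 (limma adjusted p 0.795 to 0.999 where the sign turned), values without any 1 library were -0.013 to 1.45 for CNN1, -1.05 to 0.094 for PLAU, -2.23 to 0.31 for CDK1, -2.75 to 0.30 for AURKB and -3.42 to 0.51 for CCNB1. There, mean differences from the other genes were -0.39 to 1.66 for the load and fetal programme list (0.64 with all libraries), and -1.05 to 0.16 for the glycolysis list (-0.44), which was 0.16 without the 2 libraries and 0.17 with median ratio scaling as well (camera adjusted p 0.351 to 0.899 where the sign turned).

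With a replicate block, genes changed numbered 871, 1096, 2107, 0 and 504 in the 5 comparisons, and 792, 1040, 2030, 0 and 484 of them were also called without the block. Lists numbered 19, 19, 23, 15 and 15. The labels leave open what the number marks. Between day 6 and day 10, where the pairs with the same number went together, calls that ended with the replicate block included those of CCNB1, PSAT1, RPS18, RPS23, ESRRA and KCNIP2 (limma adjusted p = 0.0775, 0.0681, 0.0532, 0.0518, 0.0525 and 0.0525). At day 6 against day 0 the ACTA1 call ended with it (limma adjusted p = 0.0544).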

Other observations

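At day 10, IGFBP4 rose from 54.2 ± 14.4 to 1360.3 ± 338 FPKM (SD, n = 3 each, limma adjusted p = 1.77e-05), and 4 of 13 genes of its list rose, 6 when adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.484 with an estimated correlation, and camera adjusted p = 0.0554 without day 10 replicate 3). Among clock genes, the repressor BHLHE41 rose from 0.868 ± 0.602 to 24.6 ± 13.7 FPKM (limma adjusted p = 7.90e-04), and CRY2, another repressor, fell from 30.7 ± 12.9 to 6.01 ± 1.54 FPKM (limma adjusted p = 0.0112). The clock list had 2 higher and 1 lower genes of 11, 3 and 2 when adjusted over the list alone, and did not pass camera (adjusted p = 0.571). The cyclin gene CCNB1 went from 1.78 ± 1.29 to 34.1 ± 29.8 FPKM (limma adjusted p = 0.0299), and the call ended without day 0 replicate 2 or day 10 replicate 1 or 3 (limma adjusted p = 0.0583, 0.118 and 0.0945).

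Among immune markers at day 10, the granzyme gene GZMA rose from 1.22 ± 0.876 to 32.2 ± 29.8 FPKM (limma adjusted p = 0.00435), while the lymphocyte gene CD2 fell from 5.13 ± 2.14 to 0.0856 ± 0.0922 FPKM (limma adjusted p = 0.00216). CSF1R, the receptor that maintains macrophages, fell from 21.4 ± 3.92 to 1.97 ± 0.951 FPKM (limma adjusted p = 0.00137). The complement and antigen presentation list had 4 lower genes of 7, the same number when adjusted over the list alone (camera adjusted p = 0.00421, adjusted p = 0.110 with an estimated correlation).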
